A study of Mus musculus with 24 samples.

How the data were processed

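The data are gene-level counts from strand-specific TruSeq mRNA libraries of mouse embryonic fibroblasts. Per the labels, reads were aligned by the authors with HISAT2 to GRCm38; the version of HISAT2, the counting program and its strand setting were not given. The deposited tables hold raw read counts per Ensembl gene for each library, with the gene's symbol, chromosome, start and end, and there is 1 table per sequencing order. All 24 libraries were used, and no column was left out. The sample titles gave the genotype, background, clone, dish and sequencing order. Clone 1 of every group carried one order number and clone 2 the other, so order and clone number coincide within a group and are balanced across groups.

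The labels call the 3 dishes of a clone technical replicates and the 2 clones of a group independent. The counts of the dishes were therefore summed per clone, which gave 8 clone sums. The chi-square per degree of freedom between dishes of a clone, over genes with at least 20 counts, ranged from 1.33 to 5.62, and no dishes had identical columns. The deviations of same-numbered clones from their group means correlated across genes with r between -0.09 and 0.26 over the 6 combinations of groups, above 0 in 5 of them, and genes are not independent replicates. The sequencing-order term of the fit takes up what clones of the same number share. Same-numbered dishes of different clones had a median r of 0.0335.

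Genes were tested with edgeR 4.0.16 under R 4.3.3. Normalization factors were TMM, and genes with low counts were removed by filterByExpr on the groups (minimum count 10, minimum total 15), which left 16000 of 49671 genes. The quasi-likelihood fit was robust, with a group term and a sequencing-order term and 3 residual degrees of freedom. All 8 clones were fitted together, so that the spread between clones was shared by the groups; the common biological coefficient of variation was 0.175. The comparisons were DM against WT in primary and in p53KD cells, the difference of these changes, and p53KD against primary cells in each genotype. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and tests were 2-sided. Errors of log2 changes (SE) are the absolute change divided by the square root of the F statistic of the test. They can understate the error for genes with few counts in a group, such as Fancg. CPM values are means of clones with their SD. A fold against a group with no counts was taken against a floor of 3 counts over the group. Ratios against 1 to 3 counts, and those of Fancg in DM cells, have exact Poisson intervals at the 95% level. Simulated counts had the same design, with 100 genes changed 4-fold and 100 changed 2-fold in 1 group. On them the test found 56% of 4-fold and 2% of 2-fold changes in the primary comparison, and 38% and 1% in the p53KD comparison. It found 43% and 2% for p53KD against primary WT cells, 50% and 4% for DM cells, and 0% of either for the difference. The real comparisons of p53KD with primary cells called 4980 and 5843 genes. The adjustment is less strict where more genes change, so the simulated shares do not carry over to them.

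Of 32 gene lists, 31 had tested genes, with 756 of their 859 symbols tested; the erythroid list had none. They cover p53 targets, cell cycle, DNA repair and tolerance, stress, matrix and other programmes of fibroblasts, markers of other cell types, Hox genes and sex-linked genes. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, and the p-values of the lists of a comparison were adjusted together. Camera with an estimated correlation and fry, which tests whether the members move one way on balance without comparing them with other genes, were run beside it. With an estimated correlation, none of the 31 lists passed in any of the 5 comparisons. Without the sequencing-order term as well, the sex-linked list passed in both comparisons of DM with WT and p53 targets in both of p53KD with primary cells. Unadjusted p was under 0.05 for 7, 2, 0, 5 and 8 lists, in the order given above, and fry called 10, 2, 0, 18 and 13 lists. The power of camera with an estimated correlation was not simulated, and the fit had 3 residual degrees of freedom. With it even the sex-linked list stood at adjusted p = 0.0758 in primary and 0.112 in p53KD cells. A list that did not pass with it is therefore not shown to be unchanged. Members were counted when adjusted over the list alone and over all genes. The lists, the comparisons, the tests, the rule for named genes and the alternatives not marked as added were fixed before the data were examined.

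Named genes were chosen by rule. For DM against WT they were the 10 largest changes in each direction among genes past the threshold, with a mean of at least 2 CPM and the same direction in both orders; for the other comparisons, 5 in each direction. Where none passed, the 3 with the smallest p in each direction were named as not past. Genes with Gm or Rik names were counted and not named. Fancg, Pcna, Trp53, Cdkn1a and Mdm2 were always reported, and up to 4 members with the smallest p were named per list, plus single members that opposed its direction.

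The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter and a stricter filter of 1 CPM, and no sequencing-order term. Others were the 24 libraries as replicates, limma voom on the 24 libraries with a clone correlation, and the 4 clones of the compared groups alone. Also run were a fit that was not robust, each clone left out in turn, and each sequencing order alone. Fits with autosomal genes alone and without the p53KD DM group, and the estimated correlation without the sequencing-order term, were added after the data were seen. Identity between copies and parent genes was measured with blastn 2.17.0+ on reference transcripts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.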

Results

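Messenger RNA was profiled by sequencing in 24 libraries of mouse embryonic fibroblasts at passage 2. Wild-type (WT) cells were compared with double-mutant (DM) cells. The DM cells are homozygous for the K164R change in PCNA, the sliding clamp of DNA replication, and lack FancG, a subunit of the Fanconi anaemia core complex that acts in DNA crosslink repair. Both genotypes were studied as primary cells and as p53KD cells, a TP53-deficient state that the labels also call immortalised. Each of the 4 groups held 6 libraries, made from 3 dishes of each of 2 independent clones. Clone 1 of every group belonged to one sequencing order and clone 2 to the other. The dishes were technical replicates, so every comparison of groups rested on 2 clones against 2 clones.

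The total count per library ranged from 13.1 M to 20.7 M, with a median of 18.5 M. The range was 16.9 M to 18.8 M in primary WT and 13.1 M to 20.7 M in primary DM libraries. It was 17.1 M to 20.2 M in p53KD libraries of either genotype. The tables held 49671 genes, and 16000 passed the low-count filter and were tested. Intervals and floors given for low counts cover counting error only. The first principal component of the clones carried 63.7% of the variance and separated p53KD from primary cells. The p53KD DM clones lay apart from each other: 206 of 11599 genes differed by over 4-fold between them, against 1 gene in primary WT, 4 in primary DM and 3 in p53KD WT cells. On the second component, with 18.9% of the variance, p53KD DM clone 1 lay at -82.7 and clone 2 at -7.63.

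Fancg, on chromosome 4 (43002343 to 43010506, GRCm38), was almost absent from DM cells of both kinds. Its mean was 7.29 ± 1.04 CPM (counts scaled to library size; SD, n = 2 clones) in primary WT, 0.0627 ± 0.0589 in primary DM, 7.49 ± 0.295 in p53KD WT and 0.0426 ± 0.0359 in p53KD DM cells. The libraries of these groups held 775, 7, 836 and 5 Fancg counts in all. The log2 change in DM against WT was -6.78 ± 0.48 (SE) in primary cells (adjusted p = 0.0295) and -7.41 ± 0.50 in p53KD cells (adjusted p = 0.0260). By counts alone the ratio of WT to DM was 113 (counting interval 54.8 to 283) in primary cells. It was 165 (70.2 to 508) in p53KD cells. Trp53, on chromosome 11 (69580359 to 69591873), encodes p53 and was low in p53KD cells. It stood at 128 ± 2.17 CPM in primary WT and 109 ± 7.57 in primary DM cells, and at 12.2 ± 1.99 and 9.61 ± 2.74 in their p53KD counterparts, which is 9.47% and 8.82% of the primary level. Trp53 fell by 3.39 ± 0.22 on the log2 scale in WT (adjusted p = 0.00294) and by 3.51 in DM cells (adjusted p = 0.00068). Between DM and WT its log2 change was -0.24 in primary cells (adjusted p = 0.615) and -0.35 in p53KD cells (adjusted p = 0.348). The Fancg call in primary cells was lost without any 1 clone of primary WT, primary DM or p53KD WT cells, and so was the call in p53KD cells. The highest adjusted p was 0.429 for primary cells, without primary WT clone 1, and 0.344 for p53KD cells. Both calls were also lost with autosomal genes alone, an alternative chosen after the data were seen (adjusted p = 0.0581 and 0.0576). When 1 clone was left out, the log2 change stayed between -8.13 and -6.24 in primary and between -8.47 and -6.85 in p53KD cells. Such a fit has fewer residual degrees of freedom, so a lost call does not show that the change rests on the clone left out.

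**Figure D1:**
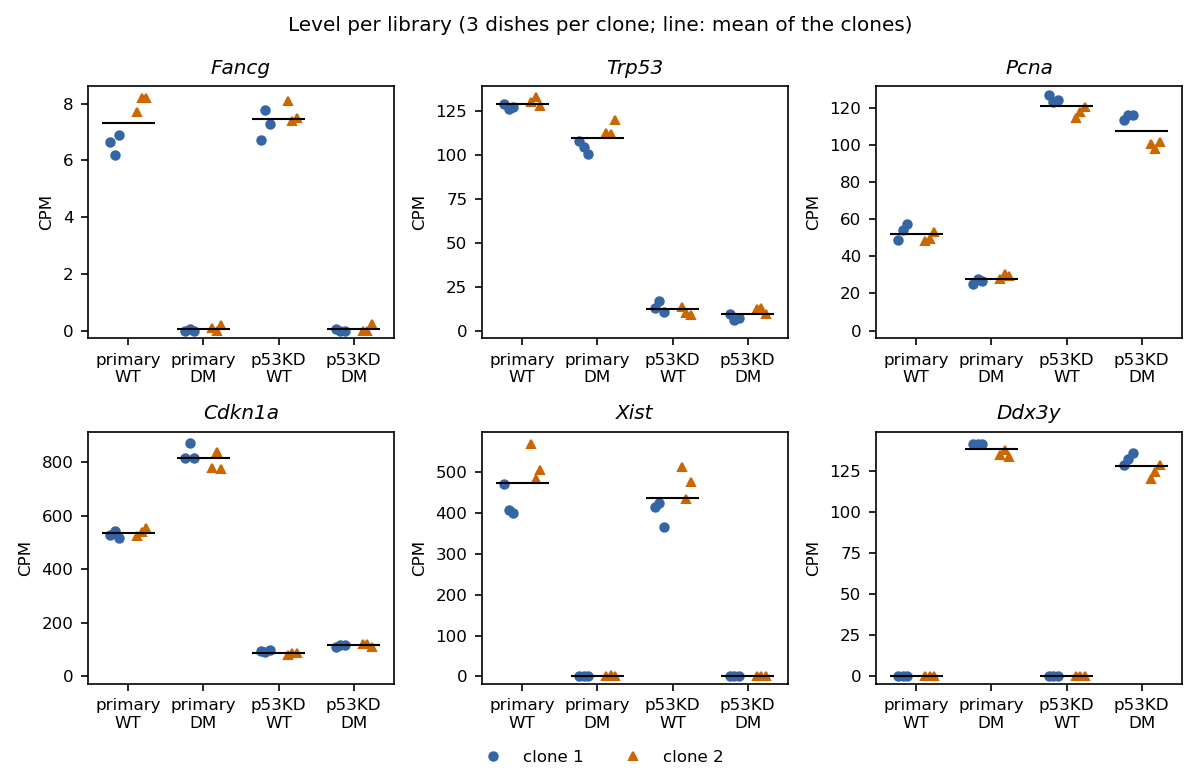
CPM of Fancg, Trp53, Pcna, Cdkn1a, Xist and Ddx3y in each of the 24 libraries, by group; circles are dishes of clone 1, triangles are dishes of clone 2 and the line is the mean of the clones. Fancg and Xist are near 0 in both DM groups, Ddx3y is near 0 in both WT groups, and Trp53 and Cdkn1a are lower in both p53KD groups than in the primary groups.

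Sex-linked transcripts divided the clones along the genotype. Xist, the noncoding RNA of X inactivation on chromosome X (103460375 to 103483217), was the opposing member of the sex-linked list and stood at 471 ± 65.7 CPM in primary WT and 440 ± 52.3 in p53KD WT cells, and at 1.18 ± 1.61 and 0.137 ± 0.0257 in the DM cells. The Y-linked genes of that list went the other way (camera adjusted p = 1e-19 in primary and 9.63e-15 in p53KD cells; adjusted p = 0.0758 and 0.112 with an estimated correlation, and 0.000249 and 0.000412 without the sequencing-order term as well). Ddx3y had 138 ± 4.22 CPM in primary DM and 128 ± 5.67 in p53KD DM cells against 0.0376 and 0.0178 in WT cells. Eif2s3y had no counts in either WT group and was at least 1836-fold higher in primary DM and at least 1653-fold higher in p53KD DM cells (floor of 3 counts over the group). Kdm5d and Uty stood at 32.9 and 28.2 CPM in primary DM cells and 31.5 and 30.5 in p53KD DM cells. All 4 WT clones thus carried Xist transcripts, all 4 DM clones carried Y-linked transcripts, and genotype and sex-linked expression coincided in the 8 clones.

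The comparison of DM with WT in primary cells is the one the series names for TP53-proficient fibroblasts. Most measured genes of the S and G2/M phase lists were lower in primary DM cells when adjusted over the list alone, and so were 16 of 26 homologous recombination and 14 of 25 checkpoint genes. Of the p53 targets 9 of 47 were higher on that basis, and of the replication-dependent histones 3 of 21. None of these lists passed with an estimated correlation (adjusted p = 0.103 for p53 targets and 0.175 for each of the others). In the G2/M phase list 48 of 52 measured genes were lower when adjusted over the list alone, with a median log2 change of -0.84 (camera adjusted p = 3.49e-53; adjusted p = 0.175 with an estimated correlation). In the S phase list 39 of 43 were lower when adjusted over the list alone, with a median of -0.83 (camera adjusted p = 7.4e-46; adjusted p = 0.175 with an estimated correlation). The medians were -1.06 for G2/M and -0.99 for S phase within the order of clone 1, and -0.60 and -0.64 within the order of clone 2. Examples are Kif11, a motor of the mitotic spindle, at -1.08 ± 0.13 (adjusted p = 0.00153 over the list alone, 0.0766 over all genes), the mitotic kinase Ttk at -1.05 ± 0.13, and Cdca7 and Uhrf1 of S phase at -1.03 ± 0.12 and -1.02 ± 0.12. Pcna, on chromosome 2 (132249162 to 132253314), stood at 51.7 ± 1.90 CPM in primary WT and 27.8 ± 1.56 in primary DM cells, a log2 change of -0.89 ± 0.10 (adjusted p = 0.00139 over the S phase list alone, 0.0766 over all genes). A Pcna copy, Pcna-ps2, stood at 0.0753 CPM in primary WT and 3.59 in primary DM cells. If the reads counted there came from Pcna, the fall of Pcna is smaller than given. The edgeR test over all genes called 0 members of either list, although 49 of the 52 and 39 of the 43 had an unadjusted p under 0.05. Without the sequencing-order term it called 27 and 18.

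The repair lists had negative medians too in primary DM cells. The homologous recombination list had 16 of 26 genes lower when adjusted over the list alone (median -0.50; camera adjusted p = 3.14e-12; adjusted p = 0.175 with an estimated correlation). Among them were the strand-exchange factors Rad54l at -1.11 ± 0.13 and Rad51 at -0.85 ± 0.11, and Brca1 at -0.96 ± 0.13. The ATR and ATM checkpoint list had 14 of 25 lower when adjusted over the list alone (median -0.43; camera adjusted p = 1.63e-11; adjusted p = 0.175 with an estimated correlation). Clspn stood at -0.89 ± 0.12 and Chek1, the checkpoint kinase, at -0.75 ± 0.14. The Fanconi anaemia list had 11 of 26 lower when adjusted over the list alone and 1, Fancg itself, over all genes (median -0.35; camera adjusted p = 2.97e-11; adjusted p = 0.157 with an estimated correlation). Fanci stood at -1.03 ± 0.11. In the DNA damage tolerance list 6 of 23 were lower when adjusted over the list alone (median -0.12; camera adjusted p = 0.00063; adjusted p = 0.175 with an estimated correlation). They included the ubiquitin ligase Rad18 at -0.60 ± 0.08 and the deubiquitinase Usp1 at -0.73 ± 0.11, both of which act on PCNA. Rad51 and Brca1 belong to more than 1 of these lists. The repair lists also share members with the cell cycle lists, among them Rad51, Exo1, Clspn and Pcna with S phase and Cdc25c with G2/M phase. Their shifts are therefore not independent of those of the cell cycle lists. Among the members of the homologous recombination, checkpoint and damage tolerance lists the edgeR test over all genes called 0, while 16, 14 and 9 had an unadjusted p under 0.05. Without the sequencing-order term it called 5, 3 and 3, all lower.

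Of the p53 targets, 9 of 47 were higher in primary DM cells when adjusted over the list alone (median 0.31; camera adjusted p = 7.41e-09; adjusted p = 0.103 with an estimated correlation). Over all genes the edgeR test called 0 of them, or 1 without the sequencing-order term, and 16 had an unadjusted p under 0.05. Cdkn1a, the cell cycle inhibitor p21 on chromosome 17 (29090979 to 29100722), stood at 533 ± 8.35 CPM in primary WT and 815 ± 29.0 in primary DM cells, a log2 change of 0.61 ± 0.09 (adjusted p = 0.0213 over the list alone, 0.078 over all genes). Dcxr, Mgmt and Fam212b had log2 changes of 0.63 ± 0.10, 0.50 ± 0.10 and 0.50 ± 0.10, each past the threshold over the list alone. Mdm2, the ubiquitin ligase of p53 on chromosome 10 (117688888 to 117710758), stood at 237 ± 11.9 and 315 ± 17.6 CPM, a log2 change of 0.41 that did not pass over all genes (adjusted p = 0.15). Replication-dependent histones had a median of 0.68 with 3 of 21 higher when adjusted over the list alone, Hist1h2bc, Hist1h1c and Hist1h3b (camera adjusted p = 5.08e-07; adjusted p = 0.175 with an estimated correlation). Their transcripts mostly lack the poly(A) tail that the library method selects. Collagen and matrix genes had a median of 0.14, with 12 of 38 below 0 (camera adjusted p = 0.00943; adjusted p = 0.455 with an estimated correlation). Past the threshold when adjusted over the list alone were 3, Loxl2 at 0.70 ± 0.10, Col8a1 at 0.87 ± 0.13 and Lox at 0.46 ± 0.09. That list did not pass without primary WT clone 1 (adjusted p = 0.0679) or primary DM clone 2 (adjusted p = 0.214).

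Past the threshold over all genes in edgeR in primary cells were 9 genes, 7 higher and 2 lower, while 2479 had an unadjusted p under 0.05. DESeq2 called 813 genes on the clone sums, and limma voom 1992 on the 24 libraries with a clone correlation. Beyond Fancg and the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty the 9 genes included Pcna-ps2, a processed Pcna copy on chromosome 19 (9283238 to 9284494), at 5.53 ± 0.31 (adjusted p = 0.0124). Sqrdl, a mitochondrial sulfide oxidase gene on chromosome 2 (122765237 to 122809569), rose from 16.6 to 39.2 CPM, a log2 change of 1.24 ± 0.09 (adjusted p = 0.0298). Kdm6a, a histone demethylase gene on chromosome X (18162575 to 18279936), fell from 42.7 to 22.5 CPM, a log2 change of -0.92 ± 0.07 (adjusted p = 0.0479). It stood at 52.8% of the WT level in primary DM and at 56.2% in p53KD DM cells. All DM clones carried Y-linked transcripts and all WT clones carried Xist. The fall of this X-linked gene therefore cannot be told apart from an effect of embryo sex. The remaining gene, Gm20056 on chromosome 16 (32408536 to 32409054), had a log2 change of 6.13 ± 0.40 (adjusted p = 0.0216) and was chosen after its values were seen. Without the sequencing-order term 142 genes passed, 118 of them lower, and 45 of those 118 belong to the S or G2/M phase lists. The count was 3 without either primary WT clone, 4 without either primary DM clone or either p53KD WT clone, 2221 without p53KD DM clone 1, 2210 without p53KD DM clone 2, and 2191 without both of the latter. The calls of Pcna-ps2, Sqrdl and Kdm6a were lost without any 1 clone of primary WT, primary DM or p53KD WT cells (adjusted p up to 0.299, 0.704 and 0.711). With autosomal genes alone, 0 genes passed in edgeR, with adjusted p = 0.0581 for Fancg, Pcna-ps2, Sqrdl and Gm20056 alike. The Kdm6a call was also lost with RLE factors (adjusted p = 0.0501). The call of Eif2s3y was lost without either primary DM clone (up to 0.263) and that of Uty without either primary WT clone (up to 0.0882). In the fit without both p53KD DM clones, added after the data were seen, 48 G2/M and 39 S phase genes were lower and 23 p53 targets higher over all genes, with Pcna at adjusted p = 0.00892, Cdkn1a at 0.0114 and Mdm2 at 0.0165. The common biological coefficient of variation was 0.0800 in that fit, against 0.175 with all clones, so the p53KD DM clones raised the spread used for primary cells.

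**Figure D2:**
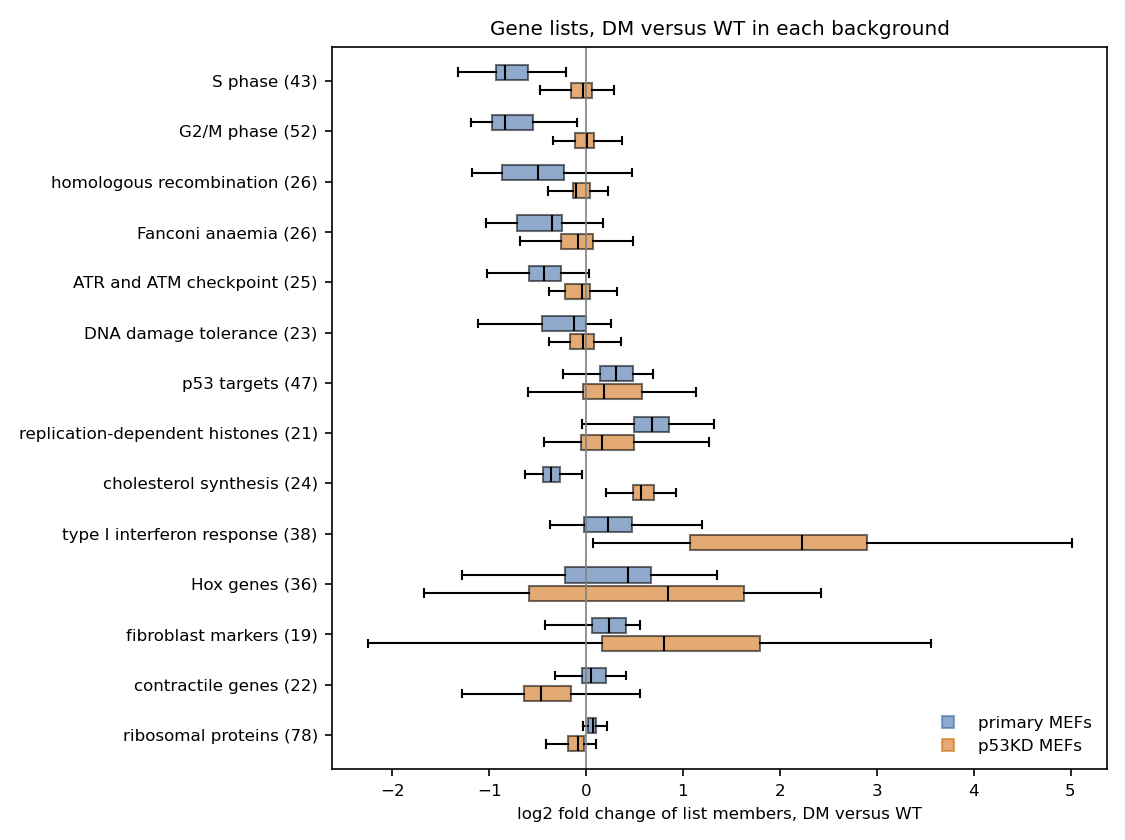
Box plots of the log2 change in DM against WT of the members of 14 gene lists, in primary cells (blue) and p53KD cells (orange). The S and G2/M phase boxes lie below 0 in primary cells, with medians of -0.83 and -0.84, and at about 0 in p53KD cells, with medians of -0.03 and 0.01.

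The same comparison in p53KD cells is the one the series names for TP53-deficient fibroblasts. When adjusted over the list alone, 3 of 38 interferon-response genes, 8 of 19 fibroblast markers, 15 of 36 Hox genes and 12 of 47 p53 targets were higher in p53KD DM than in p53KD WT cells. None of these lists passed with an estimated correlation (adjusted p = 0.313 for p53 targets and 0.714 for each of the others), and the cell cycle lists did not pass with either. All 38 measured genes of the type I interferon list had a positive log2 change, with a median of 2.23 (camera adjusted p = 2.43e-13; adjusted p = 0.714 with an estimated correlation). Without the p53KD DM group 33 of them pass the low-count filter, so the filter favoured a positive change in the rest. Over all genes edgeR called 0 of the 38, and 25 had an unadjusted p under 0.05. The median is the same with the 1 member without counts in a group at its bound. Without the sequencing-order term 35 of the 38 passed when adjusted over the list alone. The 3 past the threshold with it were the chemokine gene Cxcl10 at 1.83 ± 0.33 and the antiviral genes Rsad2 at 3.27 ± 0.69 and Ifit1 at 3.41 ± 0.71. The median within the order of clone 1 was 3.14 and that within the order of clone 2 was 0.58. Fibroblast markers had a median of 0.81, with 8 of 19 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000204; adjusted p = 0.714 with an estimated correlation). Examples are Pdpn at 0.81 ± 0.16 and Pi16 at 2.27 ± 0.46, and the opposing member was Meox2 at -2.25 ± 0.38.

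Hox genes, the positional identity genes of the embryo, had a median of 0.85 in p53KD DM against WT cells, with 15 of 36 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.000317; adjusted p = 0.714 with an estimated correlation). Hoxb8, Hoxb7, Hoxb3 and Hoxb5 of the Hoxb cluster stood at 1.80 ± 0.16, 2.06 ± 0.26, 1.59 ± 0.24 and 1.92 ± 0.29, while Hoxd10, Hoxd11 and Hoxd12 were the lower ones. The Hox list did not pass without p53KD DM clone 2 (adjusted p = 0.868). Among p53 targets 12 of 47 were higher when adjusted over the list alone (median 0.19; camera adjusted p = 0.000204; adjusted p = 0.313 with an estimated correlation). Over all genes edgeR called 0, and 19 had an unadjusted p under 0.05. Eda2r and Sulf2 stood at 1.09 ± 0.11 and 1.12 ± 0.13, and Psrc1 and Ak1 at 0.88 ± 0.17 and 0.62 ± 0.13. Cdkn1a had 89.9 ± 7.73 CPM in p53KD WT and 116 ± 3.09 in p53KD DM cells, a log2 change of 0.38 (adjusted p = 0.211). Mdm2 had 97.7 ± 2.39 and 92.4 ± 12.3 CPM, a log2 change of -0.09 (adjusted p = 0.590). Cholesterol synthesis genes had a median of 0.57 with no member past the threshold over the list alone (camera adjusted p = 0.000204; adjusted p = 0.813 with an estimated correlation). That list did not pass without p53KD DM clone 1 (adjusted p = 0.851). The S phase median was -0.03 (camera adjusted p = 0.348) and the G2/M median 0.01 (camera adjusted p = 0.913). Pcna stood at 122 ± 4.79 and 108 ± 10.7 CPM, a log2 change of -0.18 (adjusted p = 0.299). Its copy Pcna-ps2 stood at 0.197 CPM in p53KD WT and 12.2 in p53KD DM cells, so here too the fall of Pcna may be smaller than given.

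In p53KD cells 7 genes passed over all genes in edgeR, 6 higher and 1 lower, while 3258 had an unadjusted p under 0.05. DESeq2 called 949 genes on the clone sums, and limma voom 3618 on the 24 libraries with a clone correlation. All 7 also passed in primary cells in the same direction. They were Eif2s3y, Ddx3y, Uty, Kdm5d, Pcna-ps2 at 5.94 ± 0.28 (adjusted p = 0.00578), Fancg, and Gm20056 at 5.33 ± 0.37 (adjusted p = 0.0260), the last of which was chosen after its values were seen. Sqrdl, at 0.92 ± 0.09 (adjusted p = 0.0753), and Kdm6a, at -0.83 (adjusted p = 0.0649), did not pass. Across the 16000 genes, which are not independent replicates, the DM changes in primary and p53KD cells had r = 0.42. The count was 5 without either clone of primary WT or primary DM cells, 1 without either p53KD WT clone, 82 without p53KD DM clone 1 and 6301 without p53KD DM clone 2. Without either p53KD WT clone the calls of Pcna-ps2, Kdm5d and Uty were lost (adjusted p up to 0.264, 0.119 and 0.0954), and that of Eif2s3y was lost without any 1 clone of primary DM or p53KD WT cells (up to 0.171). With autosomal genes alone Pcna-ps2 passed (adjusted p = 0.0223), and Fancg and Gm20056 did not (adjusted p = 0.0576 for both).

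Sqrdl and Pcna both lie on chromosome 2, and the window of genes around Pcna was chosen after its values were seen. Within 20 Mb of Pcna, 32 of 317 genes (10.1%) had an unadjusted p under 0.05 in both primary and p53KD cells with the same direction, 21 of them higher in DM cells and 11 lower. The share among other autosomal genes was 3.78%, an odds ratio of 2.86 (95% interval 1.90 to 4.18; 2-sided Fisher's exact p = 8.97e-07), with genes not being independent replicates. Tmem230, next to Pcna on chromosome 2 (132239492 to 132247807), had log2 changes of 0.78 ± 0.10 in primary and 0.77 ± 0.10 in p53KD cells (adjusted p = 0.0766 and 0.140). Around Fancg on chromosome 4 the share was 4.52%, 9 of 199 genes, an odds ratio of 1.17 (0.523 to 2.28; Fisher's exact p = 0.581).

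**Figure D3:**
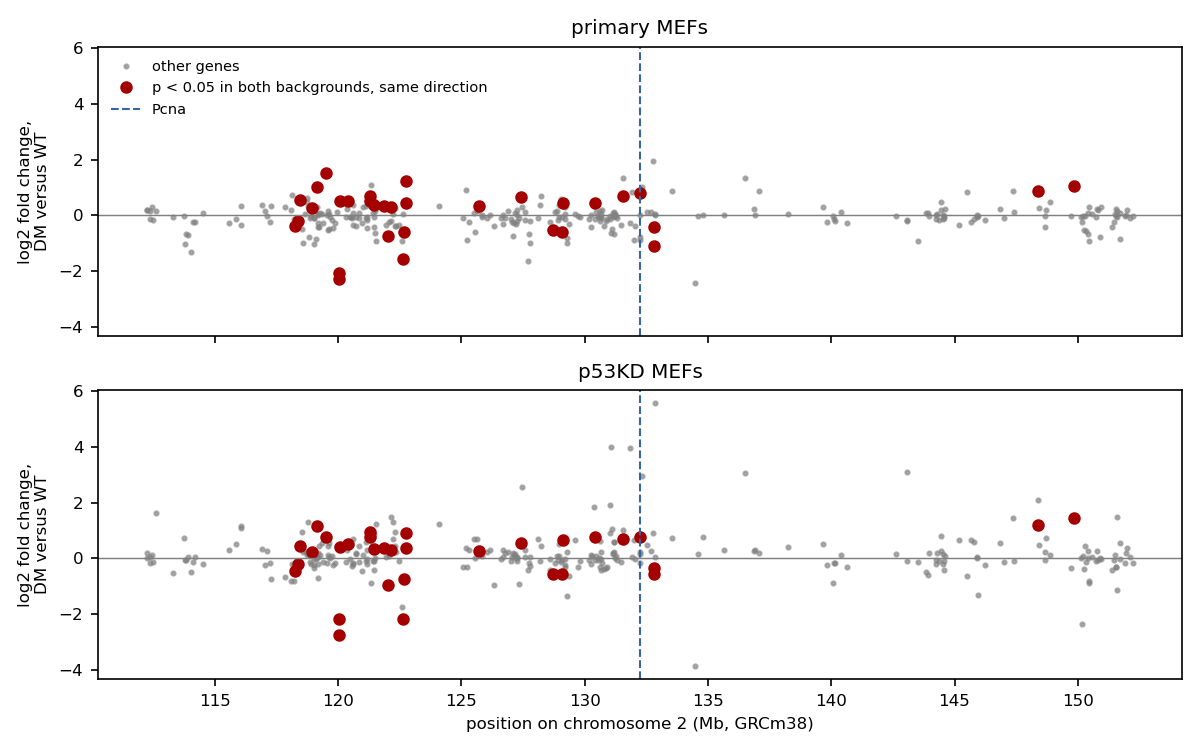
Log2 change in DM against WT of the tested genes within 20 Mb of Pcna on chromosome 2, by position in Mb, in primary and p53KD cells; the dashed line marks Pcna. Red points are the 32 genes with an unadjusted p under 0.05 and the same direction in both backgrounds.

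The difference between the DM change in p53KD cells and that in primary cells tests whether the DM change depends on the background. Genotype and sex-linked expression coincided in the 8 clones, so an effect of genotype cannot be told apart here from one of embryo sex. For cell cycle and repair lists the difference passed with the preset correlation and for none with an estimated one (adjusted p = 0.462 or 0.483). The Fanconi anaemia difference did not pass without p53KD DM clone 2 (adjusted p = 0.181). The damage tolerance difference did not pass without primary WT clone 1 (0.0661), p53KD WT clone 1 (0.0524) or p53KD DM clone 2 (0.0668). In p53KD DM cells themselves none of these lists passed, except the Fanconi anaemia list without the sequencing-order term (adjusted p = 0.0153) or without p53KD DM clone 1. That list includes Fancg, the gene that DM cells lack, at -7.41 in p53KD cells. The list was not tested without Fancg, so this does not show a change of its other members. The median difference in log2 change was 0.84 for G2/M phase, with 45 of 52 genes past the threshold when adjusted over the list alone (camera adjusted p = 2.78e-41; adjusted p = 0.462 with an estimated correlation). Among them were Cenpa at 1.01 ± 0.16 and Kif11 at 1.06 ± 0.17. It was 0.72 for S phase, with 34 of 43 genes past the threshold when adjusted over the list alone (camera adjusted p = 1.05e-29; adjusted p = 0.462 with an estimated correlation). Examples are the polymerase subunit gene Pola1 at 1.09 ± 0.16 and Uhrf1 at 1.07 ± 0.17. Homologous recombination had a median of 0.50 and 5 of 26 genes, and the ATR and ATM checkpoint list 0.36 and 8 of 25 genes, adjusted over the list alone (camera adjusted p = 6.44e-07 and 1.69e-06; adjusted p = 0.462 and 0.483 with an estimated correlation). The interferon list differed by a median of 1.84 and the cholesterol synthesis list by 0.93 (camera adjusted p = 1.18e-09 and 8.52e-10; adjusted p = 0.5 for both with an estimated correlation). No member of either passed over the list alone, and the interferon median is the same with the 1 member without counts in a group at its bound. For p53 targets the median difference of -0.05 did not pass (camera adjusted p = 0.458).

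No single gene passed the difference test over all genes in edgeR, where 1657 had an unadjusted p under 0.05. DESeq2 called 244 genes on the clone sums, and limma voom 1516 on the 24 libraries with a clone correlation. The smallest p among genes with a positive difference belonged to Igfbp5 (2.02 ± 0.25), Cxcl5 (1.99 ± 0.26) and Kif4 (0.94 ± 0.13), and among those with a negative one to Efnb1 (-0.62 ± 0.10), Kazn (-0.90 ± 0.16) and Qpctl (-0.82 ± 0.14), each with adjusted p = 0.382. The Pcna difference was 0.71 ± 0.13 (adjusted p = 0.382) and passed in DESeq2 (adjusted p = 0.00971). Leaving out p53KD DM clone 2 gave 4218 genes, and leaving out any other clone gave 0.

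The comparison of p53KD with primary cells of WT genotype sets the p53KD state, which the labels also call immortalised, against the primary state without the mutations. The series held no group with a control knockdown, so loss of p53 cannot be told apart from other differences between these cultures. Most cell cycle genes rose, and most p53 targets, matrix genes and markers of cartilage and leukocytes fell. As lists none of these passed with an estimated correlation (adjusted p = 0.0791 for p53 targets, 0.331 for leukocyte markers and 0.237 for each of the others). In the p53 target list 36 of 47 genes fell over all genes and 39 when adjusted over the list alone, with 1 rising (median -1.33; camera adjusted p = 3.97e-20; adjusted p = 0.0791 with an estimated correlation, and 0.0119 without the sequencing-order term as well). Cdkn1a changed by -2.57 ± 0.09 (adjusted p = 0.000905), Mdm2 by -1.27, the RNA-binding protein gene Zmat3 by -1.97 ± 0.07, and Eda2r by -2.99 ± 0.12, while the opposing member was Ckap2 at 0.57. In the G2/M list 49 of 52 rose and 1, Psrc1 at -1.83, fell, with the same counts over the list alone (median 1.24; camera adjusted p = 2.4e-31; adjusted p = 0.237 with an estimated correlation). In the S phase list 42 of 43 rose over all genes and 43 when adjusted over the list alone (median 1.25; camera adjusted p = 5.64e-30; adjusted p = 0.237 with an estimated correlation). Examples are the mitotic kinase gene Cdk1 at 1.43 ± 0.10, Clspn at 1.76 ± 0.12 and Pcna at 1.24 ± 0.09.

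Repair genes rose with the cell cycle lists in p53KD WT cells: 17 of 26 in homologous recombination, 16 of 25 in the ATR and ATM checkpoint list and 14 of 26 in the Fanconi anaemia list passed over all genes. When adjusted over the list alone 19, 18 and 14 did (camera adjusted p = 6.43e-08, 8.06e-09 and 2.69e-07; adjusted p = 0.237 with an estimated correlation for each). Collagen and matrix genes fell, 21 of 38 over all genes and 28 when adjusted over the list alone, with 1 rising in the latter (median -1.02; camera adjusted p = 7.78e-10; adjusted p = 0.237 with an estimated correlation). The elastin gene Eln fell from 1030 and 1444 CPM in the primary clones to 63.2 and 36.1 CPM in the p53KD clones, a log2 change of -4.67 ± 0.34, and Col8a1 and Lox changed by -1.90 ± 0.14 and -1.25 ± 0.09. Markers of cartilage and bone fell, 9 of 14 over all genes and 10 when adjusted over the list alone, with Col11a1 at -2.59 ± 0.15, while Runx2 at 0.39 ± 0.13 passed over the list alone (camera adjusted p = 8.72e-06; adjusted p = 0.237 with an estimated correlation). Leukocyte markers fell, 11 of 15 over all genes and 12 when adjusted over the list alone (camera adjusted p = 1.23e-05; adjusted p = 0.331 with an estimated correlation). Lyz2 stood at -3.87 ± 0.63, and the median was -3.99, or -3.94 with the 5 members without counts in a group at their bound. Of the Hox genes 17 of 36 fell over all genes and 18 when adjusted over the list alone, with Hoxa2 at -1.92 ± 0.25 (median -1.05; camera adjusted p = 0.00106; adjusted p = 0.331 with an estimated correlation). In the other direction 1 Hox gene passed over all genes and 2 over the list alone, and without the sequencing-order term 11 fell over all genes.

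Over all genes 4980 changed between p53KD and primary WT cells, 2413 higher and 2567 lower, or 1925 and 2916 with upper-quartile factors. The largest increases named were Tbx20 (4.43 ± 0.46) and Foxg1 (3.81 ± 0.59), both transcription factor genes, the adhesion gene Sele (3.86 ± 0.54), Tmem171 (3.83 ± 0.83) and the homeobox gene Dlx1 (3.33 ± 0.62). Fxyd6, Cdh8 and Klhdc7a had no counts in p53KD WT cells and were at least 296-fold, 217-fold and 139-fold lower there (floor of 3 counts over the group). Svop had 1 count there, a ratio of 251 (counting interval 44.6 to 9953), and the phosphatase-like gene Ptprv changed by -7.61 ± 1.42. The count fell to 21 and 12 without p53KD WT clone 1 and clone 2, and to 1825 and 491 without primary WT clone 1 and clone 2. It was 2654 and 2682 without primary DM clone 1 and clone 2, and 8531 and 8506 without p53KD DM clone 1 and clone 2. Of the 73 named or listed genes that passed, 68 and 69 did not pass without p53KD WT clone 1 and clone 2, among them Pcna (adjusted p = 0.0548 and 0.0507) and, without clone 2, Trp53 (adjusted p = 0.0507), and 14 and 36 did not without primary WT clone 1 and clone 2.

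In DM cells, too, most cell cycle genes rose and most p53 targets fell in the p53KD state (adjusted p = 0.186 for each cell cycle list and 0.0858 for p53 targets with an estimated correlation). The cell cycle medians were higher than in WT cells, by the contrast given for the difference between backgrounds, which did not pass for either list with an estimated correlation (adjusted p = 0.462) nor for any gene over all genes in edgeR, where 1657 had an unadjusted p under 0.05, against 244 calls in DESeq2 and 1516 in limma voom. The G2/M list had 50 of 52 genes rising and 1, Psrc1 at -1.21, falling, both over all genes and over the list alone (median 2.14; camera adjusted p = 4.42e-43; adjusted p = 0.186 with an estimated correlation). All 43 S phase genes rose over all genes and over the list alone (median 2.02; camera adjusted p = 2.11e-38; adjusted p = 0.186 with an estimated correlation). Cdk1 stood at 2.13 ± 0.10, Uhrf1 at 2.58 ± 0.13 and Pcna at 1.95 ± 0.10 (adjusted p = 0.000614). In the p53 target list 39 of 47 fell over all genes and 42 when adjusted over the list alone, with Ckap2 rising by 1.39 (median -1.25; camera adjusted p = 8.57e-19; adjusted p = 0.0858 with an estimated correlation, and 0.0128 without the sequencing-order term as well). Cdkn1a changed by -2.81 ± 0.09, Mdm2 by -1.77 and Zmat3 by -2.08 ± 0.07.

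Homologous recombination genes rose in p53KD DM against primary DM cells, 21 of 26 over all genes and over the list alone (median 1.59; camera adjusted p = 1.99e-10; adjusted p = 0.186 with an estimated correlation). Rad54l stood at 2.42 ± 0.13, while Mus81, Rad51d and Dmc1 fell. Of the collagen and matrix list 19 of 38 fell over all genes and 20 when adjusted over the list alone, with Lox at -1.60 ± 0.09 and Thbs1 at -1.91 ± 0.14, while Fbln1 rose by 2.08 ± 0.30 (median -0.86; camera adjusted p = 1.83e-06; adjusted p = 0.217 with an estimated correlation). The interferon list had 7 of 38 genes higher over all genes and 6 when adjusted over the list alone, with Cxcl10 at 4.13 ± 0.38 and the sensor gene Ifih1 at 1.72 ± 0.17 (camera adjusted p = 0.000953; adjusted p = 0.726 with an estimated correlation). Its median of 1.52 is the same with its 1 member without counts in a group at its bound. It was 2.25 within the order of clone 1 and -0.11 within that of clone 2, and the list did not pass without p53KD DM clone 1 (adjusted p = 0.948).

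Over all genes 5843 changed in DM cells, 2884 higher and 2959 lower; 1958 of the higher and 1883 of the lower genes also changed that way in WT cells, against 435 and 475 by independent lists. The largest increases named were Tbx20 (4.57 ± 0.49), Dlx1 (4.47 ± 0.65), Sele (4.02 ± 0.59), the peptide hormone gene Apln (3.96 ± 0.38) and Tmem171 (3.74 ± 0.90). Among the decreases, Cdh8 and Klhdc7a had 3 counts each in p53KD DM cells, ratios of 522 (counting interval 178 to 2536) and 249 (84.9 to 1211), and Prl3a1, Svop and Npy6r changed by -7.16 ± 0.73, -6.86 ± 0.46 and -6.63 ± 0.45. The count was 1405 without primary DM clone 1 and 2365 without primary DM clone 2, and 4092 to 7942 without any other clone, and 18 and 12 of the 70 named or listed genes that passed did not pass without primary DM clone 1 and clone 2.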

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

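Of the tests in this part, those of the window around Fancg and of other splits of the clones were set before their results were seen, and the tests of sex, sequencing order, library depth, copies, the Pcna window, p53KD DM clone 1 and leukocytes only after the pattern had been seen.

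In 3 of 36 tests for a library far from the other 5 of its group, a library stood apart, while chance gives about 1 in 20. The total count of primary DM clone 1 dish 1 was 13.1 M, with the nearest at 17.9 M. The mitochondrial share of p53KD DM clone 1 dish 2 was 1.26% (Wilson 95% interval 1.25 to 1.26), with the nearest at 1.44%. Fancg in p53KD DM clone 2 dish 3 was 0.219 CPM from 4 counts (Wilson interval 0.0850 to 0.562), with the nearest at 0.0544.

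For 16 lists the DM change differed between p53KD and primary cells in the test of the difference with the preset correlation, and for none with an estimated one (smallest adjusted p = 0.462). The medians of the difference were 0.84 for G2/M phase, 0.72 for S phase, 0.50 for homologous recombination, 0.36 for the ATR and ATM checkpoint, 0.26 for Fanconi anaemia and 0.19 for DNA damage tolerance. They were 1.84 for the interferon response, 0.93 for cholesterol synthesis, 0.33 for the ATF4 stress response, 0.55 for Hox genes, 0.37 for fibroblast markers and 0.92 for adipocyte markers. They were -0.15 for ribosomal proteins, -0.48 for contractile genes, -0.24 for replication-dependent histones and -0.73 for neural and glial markers. Lists that did not pass when a clone was left out were damage tolerance (adjusted p = 0.0661 without primary WT clone 1, 0.0524 without p53KD WT clone 1, 0.0668 without p53KD DM clone 2), Fanconi anaemia (0.181 without p53KD DM clone 2) and Hox genes (0.249 without p53KD WT clone 2, 0.928 without p53KD DM clone 2, and 0.0628 without the sequencing-order term). So were the ATF4 response (0.198 without primary DM clone 1, 0.0752 without p53KD DM clone 1), adipocyte markers (0.0547 without primary WT clone 1) and histones (0.332 without primary WT clone 1, 0.126 without primary DM clone 1, 0.325 without p53KD WT clone 2, 0.594 without p53KD DM clone 2). Fibroblast markers did not pass without 6 of the clones (0.0579 to 0.264, all but primary WT clone 1 and p53KD DM clone 2), nor neural markers without 5 (0.0605 to 0.0832, all but primary WT clone 2, primary DM clone 2 and p53KD WT clone 1).

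The S and G2/M phase lists were lower in primary DM clones (adjusted p = 0.175 for each with an estimated correlation) and did not pass in p53KD DM clones. Embryo sex acting alike in both backgrounds would lower the lists in p53KD cells too, where the median of their members was -0.0033. Sequencing order is argued against by the medians within orders, of which the higher was -0.63. A lower depth of the DM group is argued against by the ratio of median total counts in primary DM over WT libraries, 1.07. Yet primary DM clone 1, with fewer counts than clone 2, also had the lower lists. The relative log2 levels of S and G2/M phase were -1.36 and -1.39 in clone 1, and -1.13 and -1.15 in clone 2. Open are the DM genotype, which may act on the cell cycle where p53 is present, embryo sex acting in primary cells alone, and differences in growth between the cultures; the clones do not separate these.

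The interferon list had a median log2 change of 2.23 in p53KD DM against p53KD WT clones (adjusted p = 0.714 with an estimated correlation). Leukocytes in the cultures stay open: the summed CPM of 15 leukocyte markers had a ratio of 1.04 between p53KD DM and WT clones (5.85 and 5.68 against 5.75 and 5.37), but 46.9% of the sum was Cd68, and Lyz2 had 2.07 CPM in p53KD DM clone 1 against 0.234 and 0.232 in the WT clones. The test was first set on the number of markers with a log2 change over 1, of which there were 4 where at most 3 would have spoken against leukocytes; the sum was added after that, Ptprc was lower in both DM clones, and 5 markers had no counts in any p53KD clone. Clone 1 as the only source stays open: without it the list passed with the preset correlation (adjusted p = 6.69e-07) and not with an estimated one (adjusted p = 0.522), and against primary DM clones it did not pass without clone 1 (adjusted p = 0.948). Within the order of clone 2 the median was 0.58 against p53KD WT and -0.11 against primary DM, within that of clone 1 3.14 and 2.25, and the genotype and embryo sex may contribute too.

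Pcna-ps2 and Gm20056, copies on other chromosomes of genes of chromosome 2, were higher in DM clones. Pcna-ps2 shares 99.2% of 781 bases with Pcna, Gm20056 97.5% of 519 bases with Chp1, and Eif3j2, which did not pass at 3.11 ± 0.29 in primary and 2.68 ± 0.28 in p53KD cells (adjusted p = 0.0766 and 0.0846), 99.4% of 2379 bases with Eif3j1 (the last 4 genes chosen after their values were seen). Reads of an altered Pcna counted at the copy are a candidate explanation: the Pcna-ps2 level was 12.8% of Pcna in primary DM and 11.4% in p53KD DM clones, against 0.147% and 0.162% in WT clones, and the ratio of these shares was 0.885 while Pcna differed 3.86-fold between the DM groups. A haplotype carried along with the Pcna mutation may add to this, since genes within 20 Mb of Pcna changed alike in both backgrounds more often than others, with an odds ratio of 2.86. Around Fancg the odds ratio of 1.17 lay under the bound of 1.2 set beforehand against such a haplotype, but its interval of 0.523 to 2.28 reached past the 2 that would speak for one, so that test left it open.

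Other splits of the clones into groups of 2 and 2, fitted without the sequencing-order term, were too few for a share under 0.05. For DM against WT the real split called 404 genes in primary and 6 in p53KD cells, and for p53KD against primary 7246 in WT and 2769 in DM cells. In each of these 4 comparisons 1 of the 3 splits, the real one, gave as many genes, and the highest of the others called 0. For the difference, all 18 of 18 splits gave at least the real count of 0, and the highest other called 19; it exchanges the WT and DM labels within p53KD cells and so tests the change that both backgrounds share.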

How the results depend on the processing

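The fits with autosomal genes alone and without the p53KD DM group, and the estimated correlation with no replicate block, were chosen after the data were seen; the other alternatives were planned. In a fit without a clone, the lone clone left in its group is assumed to vary like the others. The dishes are technical replicates, so the counts with the 24 libraries as replicates and within 1 order compare clones and are large by construction. The cause of the other shifts was not tested, apart from the fit without the p53KD DM group. RLE and upper-quartile factors, the stricter filter and the fit that was not robust left all counts within 1.5 times; with RLE factors the Kdm6a call in primary cells was lost (adjusted p = 0.0501), and with upper-quartile factors 1925 of 4841 calls between p53KD and primary WT cells were higher, against 2413 of 4980. The scaling alternatives moved the median log2 change of all genes by less than 0.1. Depth limits genes near the floor of 3 counts, and the simulated test found few 2-fold changes. The common biological coefficient of variation was 0.175 with all clones and 0.0800 without the p53KD DM group. In primary cells the S and G2/M medians were -0.84 and -0.85 without that group. With it the median of both lists together was -0.83. The larger number of calls in primary cells without that group thus came with a smaller shared spread, and not with larger changes of these lists.

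For DM against WT in primary cells, 9 genes passed as reported, against 813 in DESeq2, 236 without a filter, 142 with no replicate block, 5609 with 24 libraries as replicates, 1992 in limma voom and 404 with 4 clones and no replicate block. The orders of clone 1 and clone 2 alone gave 7630 and 5074, autosomal genes 0 (no edgeR call, adjusted p = 0.0581 for Fancg, Pcna-ps2 and Sqrdl; 108 with no replicate block), and the fit without the p53KD DM group 2191 (929 with no replicate block). Leaving out 1 clone gave 3 to 2221, the latter without p53KD DM clone 1, and 2210 without p53KD DM clone 2.

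For DM against WT in p53KD cells, 7 genes passed as reported, against 949 in DESeq2, 39 without a filter, 7613 with 24 libraries, 3618 in limma voom, 9584 and 4584 within the orders, and 1 with autosomal genes (2 with no replicate block). Leaving out 1 clone gave 1, without either p53KD WT clone, to 6301, without p53KD DM clone 2. For the difference, where edgeR called 0 genes with 1657 at an unadjusted p under 0.05, DESeq2 called 244, the 24 libraries 5148, limma voom 1516 and the orders 7971 and 3579. Leaving out 1 clone gave 0 to 4218, the latter without p53KD DM clone 2.

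For p53KD against primary WT cells, 4980 genes passed as reported, against 9748 with 24 libraries, 9663 and 10135 within the orders and 8484 without the p53KD DM group; leaving out 1 clone gave 12, without p53KD WT clone 2, to 8531, without p53KD DM clone 1. For DM cells, 5843 passed, against 10019 with 24 libraries, 2769 with 4 clones and no replicate block, and 10609 and 10430 within the orders; leaving out 1 clone gave 1405, without primary DM clone 1, to 7942, without p53KD DM clone 1.

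Pcna in primary cells passed in DESeq2 (-0.90, adjusted p = 4.53e-09) and with no replicate block (-0.89, adjusted p = 0.0399), and its difference passed in DESeq2 (0.72, adjusted p = 0.00971). Leaving out 1 clone, the log2 change in primary cells was -8.13 to -6.24 for Fancg, -1.01 to -0.78 for Pcna and -0.32 to -0.19 for Trp53. In p53KD cells it was -8.47 to -6.85 for Fancg, -0.28 to -0.096 for Pcna and -0.69 to -0.057 for Trp53, which passed without p53KD DM clone 2 (adjusted p = 0.0195). The difference was -1.73 to 0.73 for Fancg, 0.60 to 0.82 for Pcna and -0.45 to 0.18 for Trp53. Between p53KD and primary WT cells the ranges were -0.29 to 0.36 for Fancg, 1.22 to 1.25 for Pcna and -3.70 to -3.12 for Trp53, and between p53KD and primary DM cells -1.68 to 0.78, 1.84 to 2.06 and -3.85 to -3.22.

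Directions turned for changes that were not called. Fancg turned in the difference (0.73) and in p53KD against primary DM cells (0.78) without primary DM clone 2, and in WT cells without primary WT clone 2 (-0.071) or p53KD WT clone 1 (-0.29). The Trp53 difference turned without p53KD WT clone 1 (0.18) or p53KD DM clone 1 (0.18). Mdm2 in p53KD cells ranged from -0.20 to 0.020 and turned without p53KD WT clone 1 (0.016) or p53KD DM clone 1 (0.020), and the Pparg difference without p53KD DM clone 2 (-0.022). The cause was not tested.

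The number of lists that passed fell from 18, 9, 16, 17 and 16 to 0 in each comparison with an estimated correlation, and to 1, 1, 0, 1 and 1 with that and no replicate block (17, 10, 15, 17 and 15 with no replicate block alone), and fry called 10 in primary cells, 2 in p53KD cells and 0 for the difference. Leaving out 1 clone gave 14 to 18, 8 to 10, 12 to 17, 15 to 17 and 14 to 17 lists.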

Other observations

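No test in this part was chosen after its result was seen, and the lists and their tests were planned. Lists not yet described for primary DM cells are given here, of which the cell cycle inhibitors did not pass. Hypoxia and glycolysis genes had a median of -0.14, and Egln3, an oxygen-sensing hydroxylase gene, passed over the list alone at -1.08 ± 0.18 (adjusted p = 0.0335; list adjusted p = 0.0141, and 0.175 with an estimated correlation). Cholesterol synthesis genes had a median of -0.36 with none of 24 past the threshold over the list alone (list adjusted p = 0.000798, and 0.647 with an estimated correlation). The cholesterol list did not pass without primary WT clone 2 (adjusted p = 0.0544) or primary DM clone 1 (0.699), nor the hypoxia list without primary DM clone 1 (0.0541). Cell cycle inhibitors went both ways: Cdkn1a and Cdkn2a, the latter at 0.58 ± 0.13, were higher, and Lmnb1, a nuclear lamina gene, was lower at -0.93 ± 0.11, with 3 of 17 higher and 4 lower when adjusted over the list alone (1 and 4 without the sequencing-order term). Their median was 0.11 while the test pointed down (adjusted p = 0.833). Smaller shifts that passed were -0.16 for the ATF4 stress response (adjusted p = 0.0129; 0.578 with an estimated correlation; 0.631 without primary DM clone 1) and 0.07 for ribosomal proteins (adjusted p = 0.0141; 0.664 with an estimated correlation; 0.628 without primary WT clone 2 and 0.0824 without primary DM clone 1).

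Leukocyte, epithelial and neural and glial markers and Hox genes passed in primary cells with no member past the threshold over the list alone. Markers of adipocytes, cartilage and bone, endothelium, mesothelium and skeletal muscle did not pass there. Leukocyte markers had a median of -0.81 (adjusted p = 0.0022; 0.449 with an estimated correlation; 0.643 without primary WT clone 1), epithelial markers -1.28 (adjusted p = 0.0430; 0.528 with an estimated correlation; 0.583 without primary WT clone 1 and 0.358 without primary DM clone 1) and neural and glial markers 0.67 (adjusted p = 0.0263; 0.528 with an estimated correlation). The neural list did not pass without primary WT clone 1 (0.105), primary DM clone 1 (0.699), p53KD DM clone 1 (0.0688) or p53KD DM clone 2 (0.0650). Hox genes had a median of 0.43 (adjusted p = 0.0398; 0.578 with an estimated correlation) and did not pass without primary WT clone 1 (0.0687), primary WT clone 2 (0.101), primary DM clone 2 (0.214), p53KD DM clone 1 (0.481), p53KD DM clone 2 (0.444) or the sequencing-order term (0.167). In p53KD DM cells ribosomal proteins had a median of -0.08 (adjusted p = 0.00132; 0.813 with an estimated correlation; 0.183 without p53KD DM clone 1), contractile genes -0.46 (adjusted p = 0.0017; 0.813; 0.364 without p53KD DM clone 1) and collagen and matrix genes 0.27 with Eln at 1.55 ± 0.30 and Thbs1 at -0.81 ± 0.13 (adjusted p = 0.0247; 0.714 with an estimated correlation). Those were the 2 collagen and matrix genes past the threshold over the list alone, against 14 higher and 2 lower without the sequencing-order term. The median relative log2 level of the collagen list was -0.08 in p53KD DM clone 1 against -0.52 in p53KD WT clone 1. It was -0.59 in clone 2 of both genotypes, so clone 2 showed no shift by this measure. The collagen list did not pass without primary DM clone 2 (0.0535) or p53KD WT clone 1 (0.0746).

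In p53KD against primary WT cells 15 of 39 genes of the senescence-associated secretion list fell over all genes and 16 when adjusted over the list alone, with Igfbp5 at -3.03 ± 0.18 and Icam1 at -5.47 ± 0.66, and 3 rose (adjusted p = 0.0093; 0.237 with an estimated correlation). Of the ATF4 response genes 13 of 29 fell over all genes and 17 when adjusted over the list alone, with Chac1 at -1.46 ± 0.13, and 2 rose on either basis, Atf3 and Slc7a1 (adjusted p = 4.48e-05; 0.370 with an estimated correlation). Of the fibroblast markers 8 of 19 fell on either basis, with Col1a1 at -1.18 ± 0.14, and 2 rose, S100a4 and Ly6a, neither of them over all genes without the sequencing-order term (adjusted p = 0.0174; 0.516 with an estimated correlation). Of the DNA damage tolerance genes 10 of 23 rose on either basis, with Rad18 at 1.30 ± 0.08, while the polymerase gene Polk fell (-1.40 ± 0.12; list adjusted p = 0.00368; 0.237 with an estimated correlation). Of the histones 7 of 21 fell on either basis (adjusted p = 0.00594; 0.331 with an estimated correlation), adipocyte markers 3 of 6 (adjusted p = 0.0428; 0.266) and skeletal muscle markers 4 of 13 (adjusted p = 0.0409; 0.261). Histones did not pass without primary WT clone 2 (0.0636), p53KD WT clone 1 (0.0543), p53KD DM clone 1 (0.0979) or p53KD DM clone 2 (0.157). Adipocyte markers did not without primary WT clone 1 (0.0555) or p53KD WT clone 2 (0.0634), nor muscle markers without primary WT clone 1 (0.0555), p53KD WT clone 1 (0.0526), p53KD DM clone 1 (0.116) or p53KD DM clone 2 (0.121).

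In p53KD against primary DM cells Fanconi anaemia and ATR and ATM checkpoint genes rose, 19 of 26 and 19 of 25 over all genes and 20 and 19 when adjusted over the list alone, and 11 of 23 damage tolerance genes rose on either basis (adjusted p = 0.186 with an estimated correlation for each). In the other direction Polk and Ube2a of the tolerance list fell over all genes, and Ube2b, and Fan1 and Ercc4 of the Fanconi anaemia list, when adjusted over the list alone. Of the cholesterol synthesis genes 8 of 24 rose over all genes, or 14 without the sequencing-order term, and 12 when adjusted over the list alone, with the receptor gene Ldlr at 0.80 ± 0.13 (adjusted p = 0.000275; 0.706 with an estimated correlation; 0.132 without p53KD DM clone 1). Of the contractile genes 9 of 22 fell on either basis, with Itga8 at -1.88 ± 0.17 (adjusted p = 0.000953; 0.706 with an estimated correlation), and so did 10 of 21 histones (adjusted p = 0.000275; 0.275; 0.0530 without p53KD DM clone 2). Cartilage and bone markers fell, 8 of 14 on either basis, with Col11a1 at -2.44 ± 0.15, and Runx2 rose by 0.87 ± 0.13 (adjusted p = 0.000944; 0.186 with an estimated correlation). Leukocyte markers fell, 8 of 15 over all genes and 9 when adjusted over the list alone, or 3 on either basis without the sequencing-order term (adjusted p = 0.00147; 0.614; 0.162 without p53KD DM clone 1), ribosomal protein genes 14 of 78 and 5 (adjusted p = 0.0136; 0.726; 0.307 without p53KD DM clone 1 and 0.0684 without the sequencing-order term), and ATF4 response genes 10 of 29 and 11, with 4 rising on either basis, Atf3, Psat1, Shmt2 and Slc7a1 (adjusted p = 0.0440; 0.706; 0.321 without primary DM clone 2 and 0.135 without p53KD DM clone 2). Immediate early genes, NRF2 targets, mitochondrial genome transcripts and endothelial and mesothelial markers passed in none of the 5 comparisons. The lists that did not pass had adjusted p of 0.0648 to 0.833 in primary and 0.0648 to 0.913 in p53KD cells, 0.229 to 0.999 for the difference, and 0.0943 to 0.878 and 0.134 to 0.990 for p53KD against primary WT and DM cells.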
